A study of Homo sapiens with 8 samples.

How the data were processed

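The series compared DNA methylation at promoters between invasive and non-invasive cells of 2 human pancreatic cancer lines, PANC1 and HPAC. Per the labels' protocols, cells were left for 24 h on a Matrigel-coated membrane above a stem cell medium holding bFGF at 10 ng/mL, EGF at 20 ng/mL and insulin at 5 µg/mL. Cells that crossed to the lower side were called invasive and cells that stayed on top non-invasive. Methylated DNA was captured with a kit built on a methyl-CpG binding protein, and at least 5 ng of DNA was amplified by PCR before labelling. Cy5 carried the captured, methylated DNA. The label protocol names the Cy3 DNA as input, while the sample characteristics call it non-methylated DNA, and which of these it was stays open. A higher log2 ratio of Cy5 over Cy3 therefore stands for more captured DNA relative to that reference.

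Each DNA sample was hybridised to 2 chips that hold different probes, so the 8 arrays make 4 samples, 1 per group. The deposited intensity values came from Feature Extraction 9.5.3.1, per the file headers, with genome build hg18. Per the file headers, the processed intensity of each channel was background-subtracted, spatially and multiplicatively detrended, and dye-normalised within the array by a linear factor. The authors' series matrix holds log10 ratios that equal the scanner software's log ratio, with a largest difference of 0, so its direction is Cy5 over Cy3. Those deposited log10 values were exactly 0 in 6.68% to 11.8% of features on the PANC1 arrays and in 15.2% to 49.8% on the HPAC arrays. The medians of these columns were 0, except -0.0119 for chip 1 of HPAC invasive.

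The log2 ratio of the processed signals was computed for each probe. The software's outlier flags covered 1.75% to 2.62% of spots on the PANC1 arrays and 19.4% to 42.9% on the HPAC arrays. Control spots, spots with an outlier flag on any of the 4 arrays of a chip, and probes whose Cy3 signal was not well above background on all 4 arrays were left out. Each array was centred on its median. A promoter value was the mean over at least 5 probes from 5500 bp upstream to 2500 bp downstream of the first-listed transcript start. Tiles of 1000 bp needed at least 3 probes. Names were updated through a RefSeq gene table of the later assembly GRCh38, used for names only: of 474411 probes, 449020 were named through an accession and 14282 through a symbol or synonym, and 11109 kept the name in the file. Coordinates are those of the files.

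Promoters and tiles were tested with limma 3.58.1 in R 4.3.3, with cell line and phenotype in the model and Benjamini-Hochberg adjustment at 0.05. The invasive and non-invasive cells of a line are a pair because they come from the same cell line. The fit has 1 residual degree of freedom plus the prior of the empirical Bayes step. No label says that the samples came from more than 1 culture, and a p-value then measures only the spread between these samples, which may be technical. The number of arrays limits the precision. Differences within a line set 1 sample against 1 and carry no test. The design, the 16 gene lists and the rule for named promoters were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, for lists with at least 5 measured members. Camera at an estimated correlation rests on the 1 residual degree of freedom. Hardly any list can pass it, so a failure there says little. List levels were set against 10000 random lists of the same size.

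The rule for named promoters takes the 10 largest passing differences in each direction, with places left filled by the promoters whose smaller difference of the 2 lines is largest, the 10 largest in each direction between the lines among those that pass, the 5 largest and 5 smallest differences within each line, and 5 tiles in each direction. Up to 4 members of a described list are named by the size of their difference. Some promoters that the rule takes are not reported here. Other promoters named in the text were chosen after their values were seen.

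The position of the spots was checked after the data were seen. In blocks of 30 rows by 57 columns, log2 Cy3 brightness was correlated with that of a PANC1 array of the same design at row shifts up to 8. In the position-checked values, each block was read at its best shift, and blocks with a best correlation under 0.8 were left out. Position-checked values were made with the outlier flags, without them, and without them with the arrays scaled to the same median absolute deviation. These 3 value sets, chip 1 alone, the PANC1 arrays alone and the tile settings of 500 bp with at least 3 probes and 1000 bp with at least 2 were all chosen after seeing the data. The spots as deposited remain the main result.

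The steps were tested on simulated data with known answers. In the promoter and tile simulations all samples had the same noise, both lines carried the full difference and every spot was in place. In 2210 simulated promoters modelled on the main values, 95 of 100 log2 differences of 2 and 16 of 100 log2 differences of 1 were recovered, with 1 false call. In 5557 promoters modelled on the position-checked values without flags, 64 of 100 differences of 2 and 0 of 100 differences of 1 were recovered, with 6 false calls. In 1175 tiles, 28 of 100 differences of 2 and 0 of 100 differences of 1 were recovered. A PANC1 array moved by 2 rows was found at that shift in 144 of 144 blocks, and an HPAC array with shuffled spots gave a median best correlation of 0.041. Alternatives covered the background, centring, scaling, loess, dim-probe filters, promoter summaries, probe minimums, empirical Bayes settings, the cell line block, base composition, tile sizes and set tests. Figures were drawn with matplotlib 3.10.9.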

Results

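Promoter methylation was profiled in PANC1 and HPAC cells, 2 lines from human pancreatic adenocarcinoma, after separation into cells that crossed a Matrigel layer and cells that did not. There were 4 groups with 1 DNA sample each, and no replicates within a group. Cy3 signals were well above background for 86.2% to 91.4% of probes on the PANC1 arrays. On the HPAC arrays this share was 47.2% and 72.8% for chips 1 and 2 of the non-invasive cells, and 85.3% and 51.7% for chips 1 and 2 of the invasive cells. The series asks how invasive cells differ from non-invasive cells.

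Only part of the deposited HPAC readings matched the brightness of the probes they were assigned to. The Cy3 brightness of HPAC invasive chip 1 matched a PANC1 array of the same design in 144 of 144 blocks at a correlation of at least 0.8. HPAC non-invasive matched in 39 of 144 blocks on chip 1 and in 90 of 144 on chip 2. HPAC invasive chip 2 matched in 0 of 144 blocks, with a median in-place correlation of 0.00222, and its best correlations lay at a shift of 2 rows in 76 blocks and of 4 rows in 68. All PANC1 blocks matched. Of the probes in the main comparison, 31.8% were in place on every array, so values are also given for position-checked spots, a set chosen after seeing the data.

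**Figure D1:**
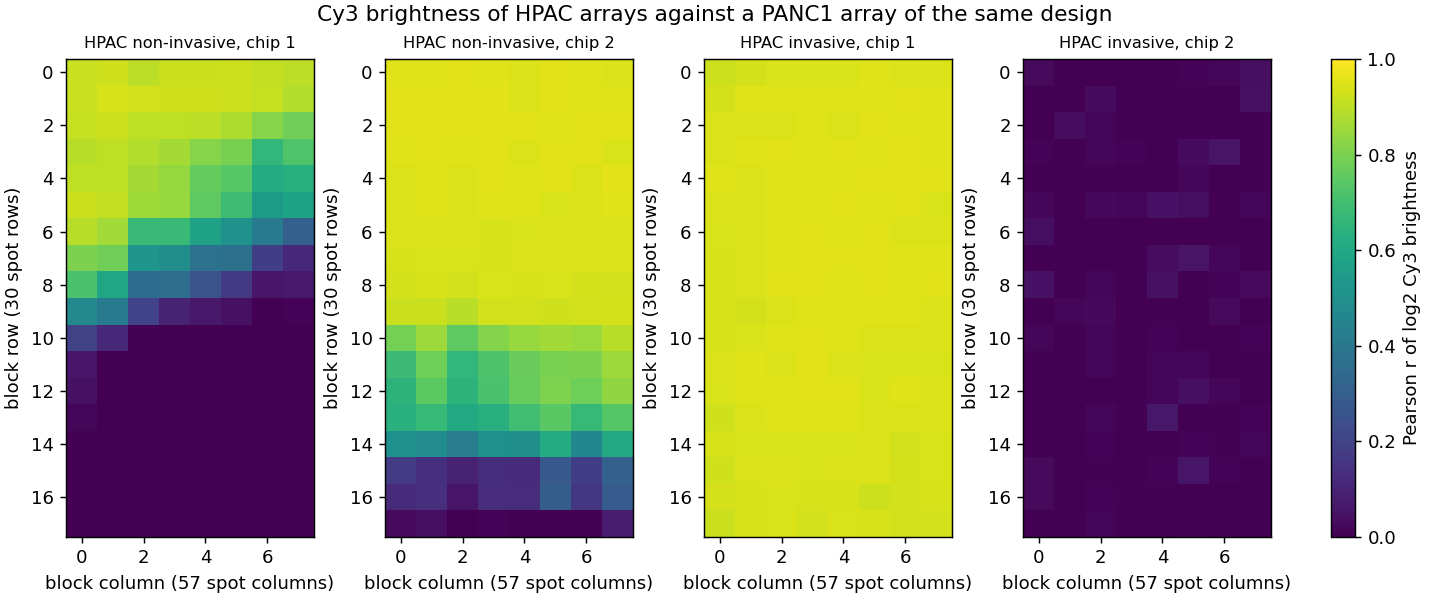
Pearson correlation of log2 Cy3 brightness between each HPAC array and the PANC1 non-invasive array of the same design, for blocks of 30 rows by 57 columns of spots; values under 0 are drawn as 0. HPAC invasive chip 1 matched in 144 blocks and HPAC invasive chip 2 in 0.

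Promoters of developmental transcription factors and HOX genes, which pattern the embryo, stood high in HPAC cells. On position-checked spots of each sample's own arrays, the median log2 ratio of developmental regulators was 0.99 in HPAC invasive cells, where 33 of 35 measured promoters were above the array median, and 0.66 in HPAC non-invasive cells, where 47 of 51 were. HOX genes had medians of 0.64 and 0.51 in those samples. In HPAC invasive cells the homeobox gene IRX1 (chromosome 5, 3643785 to 3651652, 38 probes) had 2.23, HOXA9 (chromosome 7, 27169688 to 27176579, 31 probes) 2.08, FOXD3 1.74 and IRX4 1.77. Of 10000 random lists matched on CpG content, 100% had a lower median than the developmental regulators in both HPAC samples. In PANC1 the same list had medians of 0.03 in non-invasive and 0.00 in invasive cells, with 50 and 36 of 70 promoters above the array median, and lay above 99.7% and 96.0% of the matched random lists. HOX genes had 0.14 and 0.06 there, with 33 and 25 of 39 above the array median, and lay above 100% and 99.98%. HOX promoters lie in clusters, unlike random lists, so these shares may overstate how rare the values are. The HPAC level rested on the processing: in the main values the developmental regulators had 1.04 in invasive and 0.79 in non-invasive HPAC cells, against 0.04 and 0.54 with normexp background correction and 0.08 and 0.13 without the filter on dim probes.

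Lists that check the direction of the ratio gave small values. Germline-restricted genes, silent in somatic tissue, had medians of 0.30 in HPAC invasive and 0.25 in HPAC non-invasive cells, 0.06 in PANC1 non-invasive and -0.01 in PANC1 invasive cells. Housekeeping genes had -0.08, -0.06, -0.02 and -0.03 in the same order. On probes measured in all 4 samples, 5 germline promoters were left, with medians of -0.41 in HPAC invasive and -0.02 in HPAC non-invasive cells, against -0.62 and -0.49 for 6 housekeeping promoters. On each sample's own arrays, imprinted genes had 0.25, 0.19, 0.05 and 0.04, and PEG10, a paternally expressed gene, had 1.76 in HPAC invasive cells. Genes known as methylated in pancreatic cancer had 0.23 and 0.43 in HPAC invasive and non-invasive cells, with the tumour suppressor RASSF1 at 1.28 and SOX17 at 1.47 in the invasive cells. They had -0.06 and -0.02 in PANC1 invasive and non-invasive cells. The other lists are shown in the plot of list medians. In the main values, filtered over all 4 arrays, fewer than 3 housekeeping promoters were measured and the planned contrast of germline with housekeeping genes could not be made.

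No promoter differed between invasive and non-invasive cells past the test. A difference confined to HPAC could hardly pass it. GPX5, at -2.81 within HPAC and -0.24 within PANC1, had an unadjusted limma p of 0.0135. Of 2210 promoters, 0 passed in limma with the cell line as a block, and 73 had an unadjusted p under 0.05, against 110.5 expected by chance. The 20 promoters that the naming rule takes did not pass, each with an adjusted p of 0.96, and 41 of their 108 probes were in place on every array. Higher in invasive cells of both lines were DLL1, a Notch ligand (fitted log2 difference 0.78 ± 0.32 SE), GFM1 (0.76 ± 0.31), SV2C (0.73 ± 0.31), AP1AR (0.69 ± 0.31), the glucose transporter SLC2A1 (0.61 ± 0.31), CLK4 (0.59), CPLX2 (0.57), PRRC2A (0.53) and UCMA (0.47). Lower in both were LSM6 (-1.03 ± 0.31), TMEM139 (-0.91 ± 0.32), the matrix proteoglycan VCAN (-0.88 ± 0.31), HPGDS (-0.88 ± 0.33), C1QTNF7 (-0.85 ± 0.31), PIP4K2A (-0.84 ± 0.32), ZFR (-0.74), DCTD (-0.72), ABCC5 (-0.64) and ZBTB20 (-0.59). With normexp background correction LSM6 turned to 0.65, UCMA to -0.25 and ABCC5 to 0.0023, and with the 3 best consecutive probes ZFR turned to 0.28. Without the filter on dim probes UCMA turned to -0.34 and CLK4 to -0.01, and on position-checked spots without flags CPLX2 turned to -0.36 and DCTD to 0.07. The median size of the 20 differences was 0.721, against 0.338 with normexp and 0.352 without the filter, and of the 8 measured on position-checked spots without flags 0.664 against 0.169. DLL1 had 0.10 with normexp, 0.08 without the filter, and 0.44 on those spots, or 0.07 with scaling, and without the filter SV2C had 0.11 and AP1AR 0.03.

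The count depended on the settings. Without the filter on dim probes 3 of 14479 promoters passed, EIF2B4 (-1.37), LRRC40 (-1.40) and STPG1 (-1.56), named after their values were seen. Their differences were -2.30, -2.04 and -2.998 within HPAC against -0.45, -0.76 and -0.11 within PANC1. Without the PANC1 invasive sample, in a fit with no term for the line, 103 promoters passed, and 0 without each other sample.

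Position-checked spots without flags also gave 0 of 5557 promoters in limma, with 22 at an unadjusted p under 0.05, against 277.8 expected by chance. The SD of the differences was 0.131 within PANC1 and 0.513 within HPAC. Where the PANC1 difference is near 0, the residual of the fit is about as large as its estimate. A call from HPAC alone was then hardly possible on these spots, as in the main values. Named there by the same rule, and not past the test at an adjusted p of 0.913, were EN1, a homeobox gene (0.74 ± 0.28 SE), FAM177A1 (0.67 ± 0.21) and RAD9A (0.48 ± 0.17) among the higher, and TNKS (-1.14 ± 0.41), SORBS2 (-0.83 ± 0.25) and SNAI1, a repressor of E-cadherin (-0.53 ± 0.17), among the lower. The spots of SNAI1, FAM177A1 and RAD9A were read at shifted rows. Simulated log2 differences of 1 were recovered for 16 of 100 promoters at the main values, so they were mostly not detectable in that simulation. It gave all samples the same noise and both lines the full difference. In the main values the promoter SD was 0.198 and 0.192 in non-invasive and invasive PANC1 cells, against 0.532 and 0.876 in HPAC. Recovery with these samples can therefore differ.

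Of 1175 tiles of 1000 bp, 0 passed in limma, with 59 at an unadjusted p under 0.05. These tiles held at least 3 probes. With a minimum of 2 probes, 9 of 3994 tiles of 500 bp passed and, in a setting chosen after seeing the data, 14 of 6959 tiles of 1000 bp, all of 2 probes and with fitted differences below 0. These came mostly from HPAC, running from -5.33 to -3.90 within HPAC and from -1.51 to 0.12 within PANC1. With 500 bp and at least 3 probes, also chosen after seeing the data, 0 of 288 passed. On position-checked spots without flags, 0 of 3916 tiles of 1000 bp passed in limma, with 33 at an unadjusted p under 0.05. The rule named other tiles there, led by FAM177A1 (0.83) and ST18 (-1.47). The tiles named next come from the main values, where 31.8% of probes were in place on every array. The tile with the largest shared gain lay inside IGSF21 (chromosome 1, 18309123 to 18309534, hg18), at 1.53 ± 0.47 SE and an adjusted p of 0.277. Next were tiles at PTCH1 (0.95), CLEC5A (0.87), HLA-DRB1 (0.97) and ZP4 (0.98). The tile with the largest shared loss lay inside ABCC5 (chromosome 3, 185216246 to 185216766) at -1.42 ± 0.47 and an adjusted p of 0.358, followed by TGFBI (-0.95), DOCK2 (-0.89), ZFR (-1.25) and CAMK4 (-0.72).

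Within PANC1, promoter differences were small in log2 units. On the PANC1 arrays alone, 92 of 16741 promoters (0.550%, 95% Wilson interval 0.448% to 0.673%) differed by more than 0.5, and the SD of the differences was 0.146. The interval takes promoters as independent and holds no spread between samples. The share was 3.98% in the main values and 20% with those scaled to one spread, where that of HPAC was 10.4%. In the main values the highest in invasive cells were ABLIM3 (0.82), SOWAHA (0.81), GABRG1 (0.79), CLK4 (0.74) and the phosphatase DUSP4 (0.70). The lowest were IL6, a cytokine (-1.44), PTGFR (-1.25), LSM6 (-0.91), LRBA (-0.89) and VCAN (-0.86). The IL6 promoter holds a block of 13 neighbouring probes (chromosome 7, 22731407 to 22733332, hg18, 1926 bp, from -1908 to -40 relative to the transcript start), where the Cy3 signal itself was at least 42.9-fold higher in invasive than in non-invasive PANC1 cells at the median probe. In invasive cells Cy3 was saturated at 1 of these probes and Cy5 at 6, so the IL6 difference has no exact size. The ratio at IL6 is therefore not a reading of Cy5 alone.

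**Figure D2:**
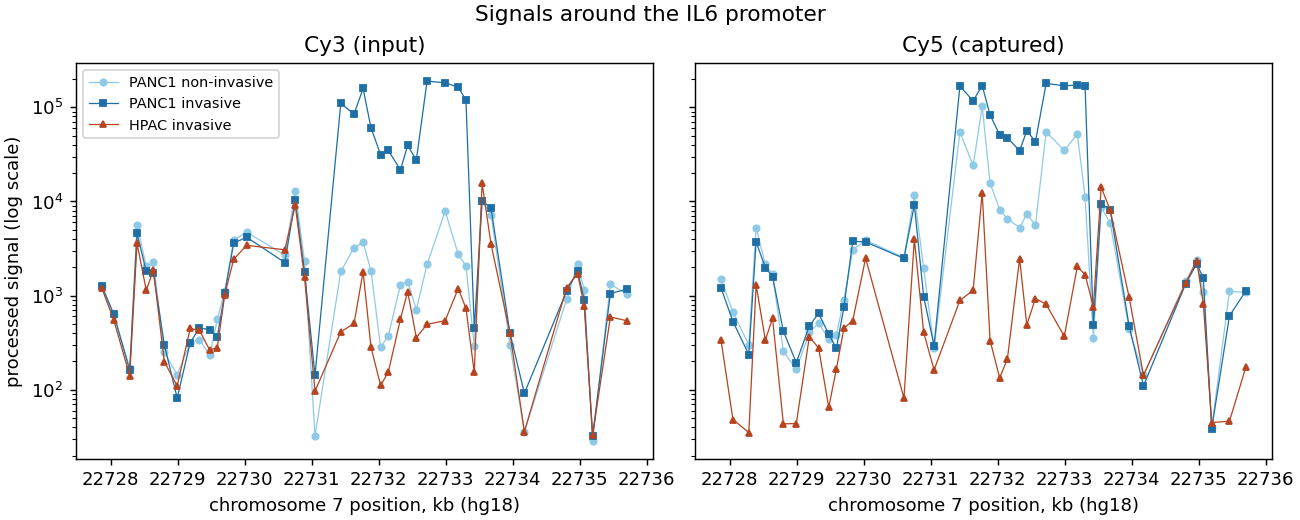
Processed Cy3 (left) and Cy5 (right) signals on a log scale (y axis) against position on chromosome 7 (x axis, kb, hg18), 1 point per probe, in the 3 samples whose spots lay in place there. Over 13 probes the Cy3 signal of PANC1 invasive cells was at least 42.9-fold that of PANC1 non-invasive cells at the median.

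Within HPAC, differences were wide in log2 units. In the main values 45.1% of 2210 promoters differed by more than 0.5, and 26.6% of 5557 on position-checked spots. With the arrays scaled to one spread these shares were 10.4% and 2.36%, below the 20% and 6.50% of PANC1. The order of the lines thus rested on the width of their ratios. Across promoters the invasive and non-invasive samples correlated at 0.616 in HPAC and 0.377 in PANC1 in the main values. On position-checked spots without flags these correlations were 0.8168 and 0.6185. In the main values LLCFC1 (2.11), EFHD1 (1.97), PENK (1.84), EPHA4 (1.80) and ESR1, the estrogen receptor (1.62), were highest in invasive cells, and GPX5 (-2.81), LAX1 (-2.66), ANXA5 (-2.60), SCN10A (-2.55) and FSTL5 (-2.50) lowest. None of the probes of LLCFC1, GPX5 and FSTL5 lay in place on every array. On position-checked spots the highest were NECTIN2 (1.69), the homeobox gene EN2 (1.35), KIFC2 (1.34), PROX1 (1.28) and FOXI1 (1.25), and the lowest MAPK10 (-2.95), POLR1F (-2.90), ZDHHC21 (-2.68), FOXP2 (-2.41) and OPN5 (-2.35). With scaling these were, in the order named, 0.76, 0.23, 0.30, 0.10 and 0.77 for the highest and -0.85, -0.91, -0.96, -0.82 and -0.78 for the lowest. The SD of position-checked promoter values was 0.846 in invasive against 0.532 in non-invasive HPAC cells.

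The differences of the lines were nearly unrelated across promoters, which are not independent replicates. Pearson's r was 0.0161 and Spearman's rho 0.0339 over 2210 promoters, and 51.3% had the same sign. Of the 111 highest promoters in each line 8 were shared, and of the lowest 6, against 5.58 for independent lists. On position-checked spots r was 0.00596 over 5557 promoters. On the PANC1 arrays alone, the PANC1 difference correlated at 0.0245 between neighbouring probes. The ratios themselves correlated at 0.1269 in non-invasive and 0.1345 in invasive cells. A weak correlation between the lines therefore cannot tell an unshared difference from a PANC1 difference that was mostly noise.

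**Figure D3:**
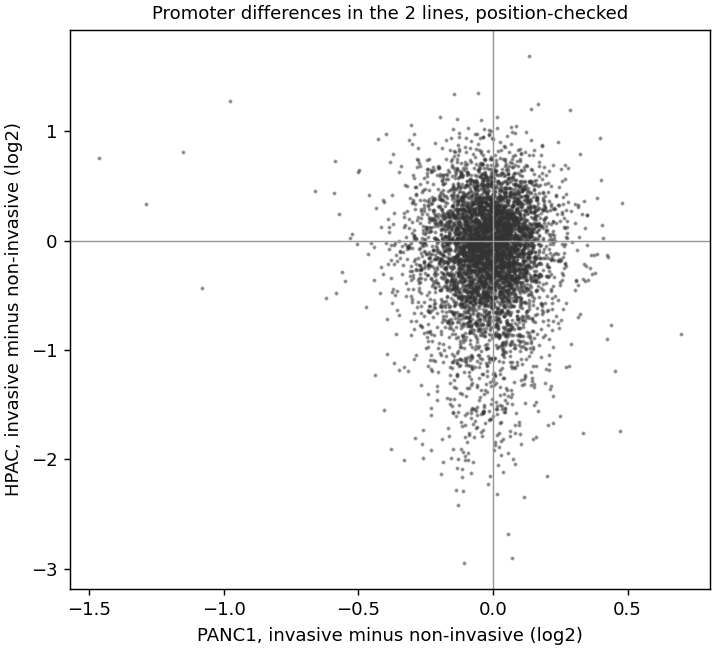
Invasive minus non-invasive log2 difference per promoter in PANC1 (x axis) and HPAC (y axis), 1 point for each of 5557 promoters on position-checked spots. The correlation was 0.00596, and the SD was 0.131 in PANC1 and 0.513 in HPAC.

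Between the lines, 0 of 2210 promoters passed in limma, with 516 at an unadjusted p under 0.05. This count rested on the processing: it was 119 of 309 on position-checked spots (44 higher in PANC1 and 75 in HPAC), 0 of 5557 without flags, where 2160 had an unadjusted p under 0.05, and 1045 of 5557 with scaling as well (486 and 559). Each line was scanned in a batch of its own, at 5 µm for PANC1 and 10 µm for HPAC, so line and batch cannot be told apart. Among the 119, GBX2 (PANC1 minus HPAC -1.78 ± 0.25 SE), FZD8 (-1.72), IRX4 (-1.68), HOXA4 (-1.65), LY6E (-1.40), LRFN2 (-1.37), FOXD3 (-1.37), HCRTR1 (-1.36), MNX1 (-1.36) and TFAP2A (-1.31) were higher in HPAC. TRAF5 (2.13 ± 0.32), FAM98A (1.67), SRFBP1 (1.66), IL6 (1.43), ATR (1.40), PSMD6 (1.35), SLC7A2 (1.29), SORBS2 (1.27), PHC2 (1.20) and IKBKE (1.18) were higher in PANC1. Their adjusted p ran from 0.00133 to 0.0247. Without flags and with scaling FOXD3 turned to 0.83 and GBX2 stood at -0.10. IL6 had 1.39 in non-invasive and -0.04 in invasive PANC1 cells, so its value came mostly from the non-invasive sample. Over the block of 13 probes the median log2 ratio of that sample was 3.08. The Cy3 signal of these probes was itself raised in PANC1 invasive cells.

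Of 11 lists with at least 5 measured promoters, 0 passed for invasive against non-invasive cells with camera or fry. Developmental regulators had the lowest adjusted p, 0.139, with 17 of 25 members above 0. On position-checked spots without flags the list passed camera, with 34 of 58 members above 0, a median of 0.06 and an adjusted p of 0.0444. It did not pass with fry (adjusted p = 0.822) or with an estimated correlation (adjusted p = 0.952), where hardly any list could. With scaling its HPAC median difference turned from 0.15 to -0.08. No member passed, over all promoters or adjusted over the list alone. EN1 (0.74), EN2 (0.65) and IRX4 (0.47) had the largest differences. Integrins and laminin receptors had 6 of 19 members above 0, with ITGA2 at -0.46. Matrix proteases had 7 of 12, with CTSB at 0.36 and MMP14 at -0.30. Mesenchymal genes had 8 of 17, epithelial adhesion genes 6 of 15, cytokines 3 of 12 and genes known as methylated in pancreatic cancer 13 of 24. None of these 6 lists passed.

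Between the lines, developmental regulators were lower in PANC1 in 24 of 25 members, with a median difference of -0.86 and a camera adjusted p of 3.17e-07. The call was lost with fry (adjusted p = 0.23). With an estimated correlation the adjusted p was 0.695, but hardly any list could pass that test. Adjusted over the list alone 14 members passed, and 0 over all promoters. On position-checked spots without flags HOX genes (-0.49, adjusted p 0.0229) and genes known as methylated in pancreatic cancer (-0.46, adjusted p 0.0129) passed camera as well, with RASSF1 at -1.58, DKK2 at -1.35, HOXB5 at -2.39 and HOXA9 at -1.79. None of the 16 lists passed with an estimated correlation, where the lowest adjusted p was 0.693. The pancreatic cancer list went from an unadjusted camera p of 0.00161 to 0.177 there, though its estimated correlation of -0.0435 was below the preset 0.01. That failure therefore does not speak against the lists. With fry, motility and guidance genes (adjusted p = 0.0168) and the pancreatic cancer list (0.0335) passed. With scaling as well, the HOX median turned to 0.02 and HOXA9 to 0.04, the pancreatic cancer list had -0.23 (camera adjusted p = 0.063), and developmental regulators had -0.23 (camera adjusted p = 0.00492). The call for developmental regulators was lost with fry (adjusted p = 0.0696). Its adjusted p was 0.819 with an estimated correlation, where hardly any list could pass.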

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

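Every test of an explanation here was chosen after its result was seen, except that of a dye response shared by all arrays. Gene lists whose median invasive minus non-invasive difference had opposite signs in the lines are given below. The lines were not tested for a difference, and each rests on 1 sample per group.

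Stem cell markers had a median difference of 0.616 within HPAC and -0.032 within PANC1 in the main values, and developmental regulators 0.431 and -0.061. Imprinted genes had 0.083 and -0.076, protocadherins 0.186 and -0.094, integrins and laminin receptors -0.191 and 0.043, and receptors for the factors of the medium -0.045 and 0.045. On position-checked spots without flags, the contrast was gone for stem cell markers (0 and -0.04), imprinted genes (-0.044 and -0.03) and protocadherins (-0.005 and -0.004). There, the HPAC and PANC1 medians were 0.147 and -0.031 for developmental regulators, 0.204 and -0.007 for methylation enzymes, 0.054 and -0.072 for HOX genes and 0.045 and -0.008 for matrix proteases. They were -0.065 and 0.007 for epithelial adhesion genes, -0.126 and 0.017 for germline genes, -0.104 and 0.011 for receptors of the medium's factors and -0.133 and 0.003 for integrins. With scaling as well, the HPAC medians of developmental regulators, HOX genes and methylation enzymes turned to -0.082, -0.108 and -0.089.

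Cy3 readings of HPAC invasive chip 2 were unrelated to the probes in place. The median best correlation over row shifts was 0.796, which argues against failed hybridisation and goes with a measuring grid laid 2 or 4 rows away. It cannot exclude other human DNA, because the reference was itself DNA of another line. HPAC invasive chip 1, in place, correlated at 0.9425 with that PANC1 design. For the 105 blocks of HPAC non-invasive chip 1 that were out of place the median best correlation was 0.465, too low to settle on whole-row shifts and too high to exclude them. No biological explanation was tested.

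PANC1 ratios were narrow, with an SD of mean promoter ratios 0.204 times that of HPAC. Within groups of like CpG content the lines' ratios correlated at 0.377, with a slope of 0.0906, which is consistent with a weak enrichment of the same promoters at like CpG content. Across CpG content, weak enrichment alone would let PANC1 ratios rise as those of HPAC did, and the rank correlation with CpG content was -0.073 in PANC1 against 0.541 in HPAC, which argues against it as the whole account. A dye response of each probe that all arrays share was predicted not to carry to the next probe. Neighbouring probes correlated at 0.15, against 0.359 for the same probe. Only the mean of each CpG count was removed, not GC content, which neighbouring probes may share, so the test cannot decide. Fewer methylated promoters in PANC1 cannot be told apart from weak enrichment, since each line has a scan batch of its own.

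Upstream of IL6, Cy3 of PANC1 invasive cells exceeded that of non-invasive cells by a median log2 of 5.42 over 13 probes, against -0.03 in the flanks. In invasive cells Cy5 was saturated at 6 of these probes and Cy3 at 1, and over the 7 unsaturated probes Cy3 was 33.1-fold and Cy5 6.53-fold higher, with log2 ratios of 2.99 in non-invasive and 0.52 in invasive cells. A methylation difference alone would leave Cy3 alike if it was input, or lower Cy5 if Cy3 was non-methylated DNA, and the median Cy5 log2 difference over the 13 probes was at least 2.41, which argues against it in both cases. The sharp edges are consistent with DNA of this region, such as a construct or amplicon, added to the labelled sample. Where such DNA came from was not tested. In non-invasive cells Cy5 exceeded Cy3 over the same 13 probes by a median log2 of 3.08. Whether that sample held such DNA too was not tested.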

How the results depend on the processing

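The settings on position-checked spots, chip 1 alone, the PANC1 arrays alone and 2 tile settings (500 bp with at least 3 probes, 1000 bp with at least 2) were chosen after seeing the data. The absence of promoter calls between invasive and non-invasive cells held in 21 of 26 alternatives and the absence of tile calls in 24 of 26. Of the 20 promoters that the naming rule takes, 3 changed sign with normexp, 3 without the dim-probe filter, and 2 of the 8 measured on position-checked spots without flags. The cause was not tested for the values below, except where fewer promoters or other samples entered. Cy3 was well above background for 47.2% of probes on HPAC non-invasive chip 1, which limits the promoters that can be measured.

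With normexp at an offset of 50, 3 promoters passed between the lines, 0.136% differed by more than 0.5 within PANC1 and 49.3% within HPAC, the correlation of the lines was -0.124, and developmental regulators had medians of 0.537 in HPAC non-invasive and 0.041 in HPAC invasive cells. Scaled to one median absolute deviation, the shares were 20% in PANC1 and 10.4% in HPAC, and developmental regulators had -0.11 in PANC1 invasive, 0.46 in HPAC non-invasive and 0.44 in HPAC invasive cells. Quantile normalization gave shares of 18.9% and 20.2%. Loess within the array gave 205 promoters between the lines and 37.4% within HPAC. With GC and CpG loess in the fit with the cell line block, 104 promoters and 2 lists passed between the lines (both lists at an adjusted p of 0.83 with an estimated correlation), and 36.7% differed within HPAC.

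Without the dim-probe filter, 3 promoters passed between invasive and non-invasive cells and 48 between the lines, 34.1% differed within HPAC, the lines correlated at 0.0633, 3 lists passed between the lines (each at an adjusted p of 0.78 with an estimated correlation), and developmental regulators had 0.13 in HPAC non-invasive and 0.08 in HPAC invasive cells. With both channels above background, 1 promoter passed between invasive and non-invasive cells, CLEC5A (0.15 within PANC1 and -2.73 within HPAC), and 279 between the lines, with shares of 1.00% in PANC1 and 36.0% in HPAC. With at least 10 probes, 1 promoter (PHC2, -0.28 within PANC1 and -1.97 within HPAC) and 41 between the lines passed. With the 3 best consecutive probes, 3 promoters (ALX1, APCS and CCDC28B, -0.40 to -0.05 within PANC1 and -4.05 to -3.51 within HPAC) and 523 between the lines passed. The counts between the lines were 12 with promoter medians, 5 with a trended prior, 244 with a robust prior and 162 at an adjusted p below 0.1. With a minimum of 2 probes, tiles of 500 bp gave 9 calls and tiles of 1000 bp 14, and with at least 3 probes tiles of 500 bp gave 0, so the calls came with the lower minimum.

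Position-checked spots gave 119 promoters between the lines, shares of 1.29% and 30.4% within PANC1 and HPAC, a correlation of 0.0797, and 0.12 for developmental regulators in PANC1 invasive cells. Without flags, the shares were 0.324% and 26.6%, and 1 list passed between phenotypes and 3 between the lines (adjusted p of 0.952 and 0.693 with an estimated correlation). With scaling as well, 1045 promoters passed between the lines, the shares were 6.50% and 2.36%, and developmental regulators had 0.43 in HPAC non-invasive and 0.36 in HPAC invasive cells. Chip 1 alone gave 1 list between phenotypes, the developmental regulators, with an adjusted p of 0.996 at an estimated correlation. The PANC1 arrays alone gave 0.550%. In the main values, 0 lists passed between the lines with an estimated correlation and 0 with fry, against 0 and 2 on position-checked spots without flags. Hardly any list could pass with an estimated correlation. The 1% highest and lowest promoters shared 0 between the lines. Such short lists would share few promoters by chance, so this count cannot tell whether the lines agree.

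The cell line is the pairing. The fit with no replicate block gave 0 promoters and 0 tiles. Leaving out each sample in turn used a fit without the block, which assumes that the lone sample varies like the others. It gave 0 to 103 promoters, the highest without PANC1 invasive, and 0 tiles. Leaving out a whole line leaves no residual degree of freedom and gave no test.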

Other observations

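In PANC1 cells, some promoters of the gamma protocadherin cluster and that of SOX30, a testis transcription factor, had among the highest log2 ratios on position-checked spots. PCDHGA12 (chromosome 5, 140784943 to 140792103) had 0.86 in non-invasive and 0.60 in invasive cells, PCDHGA3 0.78 and 0.58, and SOX30 0.81 and 0.57. The protocadherin list had a median of 0.07 in both samples, and 99.9% and 100% of random lists of like CpG content had lower medians. High values were not particular to PANC1. In HPAC invasive cells SOX30 had 2.44, and the protocadherin list had 0.22, above 99.7% of such random lists. On probes shared by both PANC1 samples the list had a median difference, invasive minus non-invasive, of -0.105, with 8 of 37 promoters higher in invasive cells, and 0.12% of random lists of the same size and like level had a lower one. Protocadherin promoters lie in clusters, unlike random lists, so these shares may overstate how rare the values are. The difference sets 1 sample against 1. The median difference was -0.094 over 5 promoters in the main values, above 25.7% of random lists, and -0.004 over 8 on position-checked spots of all 4 samples without flags, above 65.1%. PCDHGA12, PCDHGA3 and SOX30 were picked after their values were seen.

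Runs of at least 3 neighbouring probes beyond a log2 ratio of 2 on the PANC1 arrays were found at 4 places. One is the IL6 region, found in non-invasive cells, where 13 probes averaged 3.53 against 0.40 in invasive cells. Cy3 was raised there in the invasive cells. At STK31, a germ cell gene, 3 CpG-rich probes (chromosome 7, 23716260 to 23716566, hg18, from -80 to 20 relative to the start) averaged 2.35 in non-invasive and 1.39 in invasive cells. At NNAT, an imprinted gene, 3 probes (chromosome 20, 35582277 to 35582532) averaged 2.16 and 2.52. At DNAJA4, 3 probes (chromosome 15, 76344335 to 76344760) averaged 0.04 in non-invasive and -2.70 in invasive cells. Each is 1 sample against 1.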
